A study of Ostrinia furnacalis with 9 samples.

How the data were processed

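Chromatin from heads of Ostrinia furnacalis larvae was immunoprecipitated with antibodies against H3K9me3 or H3K27me3 and sequenced at 3 stages, non-diapause, pre-diapause and diapause. The series holds 9 samples, 1 for each mark and stage and 1 input for each stage. The 6 immunoprecipitated samples each had 1 deposited list of broad peaks. The 3 input samples had no peak list and were not used here. Stage and mark were taken from the sample titles.

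Bowtie2, Picard, MACS2, ChIPseeker and deepTools are named in the submitters' processing notes, without versions or settings. The genome build was not given in the sources used here, and positions are those of the deposited lists, written 1-based. The names of the sequences have the form of RefSeq names, nearly all of scaffolds. A single sequence with another kind of RefSeq name was taken as the mitochondrial genome of the species, from background knowledge of its name and length and not from the files. The lists have 9 columns and no header, and the columns were read as the broad-peak layout of MACS2. The deposited score of a peak was 10 times its −log10 q, cut to a whole number, in all but 6 of the 29330 peaks, and it never differed by more than 1. The deposited fold enrichment is the ratio of the immunoprecipitated library to its background averaged over the peak, and whether the input served as background is not stated in the sources used here. The deposited −log10 p and −log10 q values are those of the authors' peak caller. The smallest −log10 q was 2.01, and weaker places were not in the lists. Whether a list was called on 1 library or on pooled libraries is not stated in the sources used here. The short sample descriptions end in digits that could be replicate numbers, and they were not used. Fold and −log10 q belong to the authors' lists, and they were used to describe, rank or filter peaks within a list. A fold in one list is not on a scale shared with another.

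Peak lists carry no read totals, so the depth behind each list is unknown. A place without a listed peak had no call past the authors' threshold, which does not show that the mark was absent. With 1 list for each stage and mark, differences between stages could not be set against replicate error, so no test between stages was made and no p-value is given. Shares of peaks carry exact Clopper-Pearson 95% intervals, which cover counting error only, treat neighbouring peaks as independent and leave out differences between animals.

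Lists were compared by the share of peaks of one list that shared at least 1 bp with a peak of another. The share expected from chance came from 1000 random placements, in which each peak of the first list kept its width and was moved within its own sequence. Sequence lengths were not used here, so the span of a sequence ran to the farthest peak end in any list, and the spans of the 1419 sequences came to 375 Mb. Peaks of several lists that touched one another were merged into places, and each place was classed by the lists with a peak in it. Windows of 100 kb with more peak midpoints than any window in 1000 placements over all spans were called dense. On the scaffold with the most dense H3K27me3 windows, counted over the 3 stages, the stretch from the leftmost to the rightmost of them is called the block. Peaks of a list were also split into 10 parts of equal size by −log10 q.

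Both procedures were checked on simulated data made from the non-diapause H3K9me3 list. Lists with 0, 30, 60 and 90% of peaks copied gave shares of 3.85, 31.7, 60.4 and 90.0%. All 10 windows of a planted block of 150 peaks were found, with 0 other windows. The planted block was denser than the block reported in the results, and fewer placements were used, so finding sparser blocks was not checked. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

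The rules for naming peaks, the stage comparisons and the main alternatives were fixed before the data were examined. For each mark the text names the 5 peaks with the highest fold in each direction between diapause and non-diapause, 2 in each direction for the other pairs of stages, and the 5 peaks found at all 3 stages whose lowest fold was highest. These were the rules for the case that genes could not be placed. The gene table used here holds 17154 genes and places 0 of them on a named sequence. Genes near peaks, the position of peaks relative to genes and 23 planned gene lists were therefore not analysed here. The dense windows, the split by strength and the account of the mitochondrial sequence were chosen after the data were seen, and peaks in them are named outside the rule.

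The alternatives fixed beforehand were a minimum −log10 q of 3, an overlap of at least 50% of the peak, and lists shortened to the 3505 strongest peaks. Alternatives chosen after seeing the data left out the mitochondrial sequence, kept only peaks that overlapped no peak of the other mark at any stage, or counted the peaks of the block under the stricter and the shortened lists.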

Results

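The Asian corn borer, Ostrinia furnacalis, is a moth whose larvae can enter diapause, a hormonally controlled arrest of development. The series asked how repressive histone marks in the larval head differ between stages of this arrest. The stock was reared at 27 °C with 16 h of light and 8 h of dark. Newly moulted fourth-instar larvae became pre-diapause after 20 days at 20 °C with 12 h each of light and dark, and diapause larvae were held so for at least 30 days. No separate rearing is given for non-diapause larvae, so the other 2 stages differed from stock conditions in temperature and day length as well as in state. Heads of these larvae and of non-diapause larvae were profiled by ChIP-seq for H3K9me3, a mark known from constitutive heterochromatin and silenced repeats, and for H3K27me3, the mark laid down by Polycomb proteins. There was 1 peak list for each mark and stage, so no difference between stages could be set against replicate error. All intervals are exact binomial 95% intervals and cover counting error only.

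Pre-diapause heads had the longest peak list for both marks. H3K9me3 had 4486 peaks at non-diapause, 7226 at pre-diapause and 3505 at diapause, which covered 2.93, 5.25 and 2.34 Mb. H3K27me3 had 3760, 6540 and 3813 peaks, which covered 2.39, 4.46 and 2.51 Mb. Pre-diapause lists were thus 1.61 times as long as non-diapause lists for H3K9me3 and 1.74 times for H3K27me3. Peaks were short for these marks, with a median width between 489 and 537 bp in the 6 lists, and at most 3.25% of a list was wider than 2000 bp. The median of the authors' fold enrichment was 3.40, 3.33 and 2.57 in the H3K9me3 lists in stage order, and 3.25, 3.31 and 2.99 in the H3K27me3 lists. The depth of the libraries is unknown, so list lengths describe these lists and their calling and not the amount of a mark.

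Between non-diapause and diapause, H3K9me3 peaks called were fewer and in part at other places. Of the diapause H3K9me3 peaks 57.9% (56.3–59.6) overlapped a non-diapause peak, and of the non-diapause peaks 45.6% (44.1–47.1) overlapped a diapause peak. Random placement gave on average 3.22% and 2.55%. A set of 2441 non-diapause peaks had no diapause peak, and 1474 diapause peaks had no non-diapause peak.

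The strongest H3K9me3 peaks called at non-diapause and not at diapause were strong at pre-diapause too. On scaffold NW_021131933.1 at 124455–124995 the fold was 13.1 at non-diapause and 15.3 at pre-diapause. At NW_021137822.1 33757–34241 it was 12.0 and 13.2, and at NW_021131648.1 425803–426334 it was 11.9 and 11.9. These 3 places also had H3K27me3 peaks at non-diapause, with folds of 11.7, 11.2 and 10.3, and no diapause peak of that mark. The other 2 named peaks, NW_021135502.1 1113–1955 with a non-diapause fold of 11.1 and NW_021137764.1 16221–16953 with 10.6, had diapause H3K27me3 peaks with folds of 3.27 and 3.32. The strongest H3K9me3 peaks called at diapause and not at non-diapause, in a list whose folds are on their own scale with a median of 2.57, lay at NW_021133857.1 387–711 (fold 5.46), NW_021137676.1 311243–311597 (5.45), NW_021135815.1 285856–286221 (5.35), NW_021131411.1 541261–541604 (5.32) and NW_021131322.1 335793–336149 (5.32). None of these 5 had an H3K27me3 peak at diapause, and 4 of them had an H3K9me3 peak at pre-diapause. H3K27me3 was called at earlier stages at all but the last of them. Its pre-diapause folds were 4.07, 4.54, 2.91 and 4.88 in the order given. NW_021137676.1 and NW_021135815.1 also had non-diapause H3K27me3 peaks, with folds of 5.27 and 2.48.

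H3K27me3 lists of non-diapause and diapause were of nearly equal length, and over 1 in 3 peaks of each had no partner in the other. Of the diapause H3K27me3 peaks 60.5% (59.0–62.1) overlapped a non-diapause peak, and of the non-diapause peaks 61.8% (60.3–63.4) overlapped a diapause peak, against 3.06% and 3.21% under random placement. The diapause list was longer by 53 peaks as deposited, and with −log10 q of at least 3 it held 3273 peaks against 3348 at non-diapause. A set of 1435 non-diapause peaks had no diapause peak, and 1505 diapause peaks had no non-diapause peak. The strongest H3K27me3 peak called at non-diapause and not at diapause lay at NW_021131106.1 132114–133473, with a fold of 12.0. H3K9me3 peaks at that place had folds of 16.2 at non-diapause, 20.2 at pre-diapause and 1.59 at diapause. NW_021136315.1 85974–86476 had a fold of 8.89, and the remaining 3 named peaks were those on NW_021131933.1, NW_021137822.1 and NW_021131648.1. The strongest diapause H3K27me3 peak without a non-diapause peak lay near the start of scaffold NW_021131459.1, at 83–456, with a fold of 8.87. That place had a pre-diapause H3K27me3 peak with a fold of 9.64 and a pre-diapause H3K9me3 peak with a fold of 10.0. NW_021133079.1 384–761 (fold 5.96) and NW_021132285.1 221534–221962 (5.43) had a peak in the diapause H3K27me3 list and in no other list. NW_021131363.1 17180–17527 (5.31) and NW_021132087.1 142408–142880 (5.05) completed the named set.

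Peaks without a partner were not only weak ones of their list. Among the strongest 10% of non-diapause peaks by −log10 q, 28.3% (24.2–32.7) for H3K9me3 and 19.9% (16.0–24.3) for H3K27me3 had no diapause peak. Among the strongest 10% of diapause peaks, 10.5% (7.53–14.2) and 3.93% (2.21–6.39) had no non-diapause peak. In the weakest 10% of non-diapause peaks the share without a diapause peak was 72.8% (68.4–76.8) for H3K9me3 and 56.9% (51.7–62.0) for H3K27me3.

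**Figure D1:**
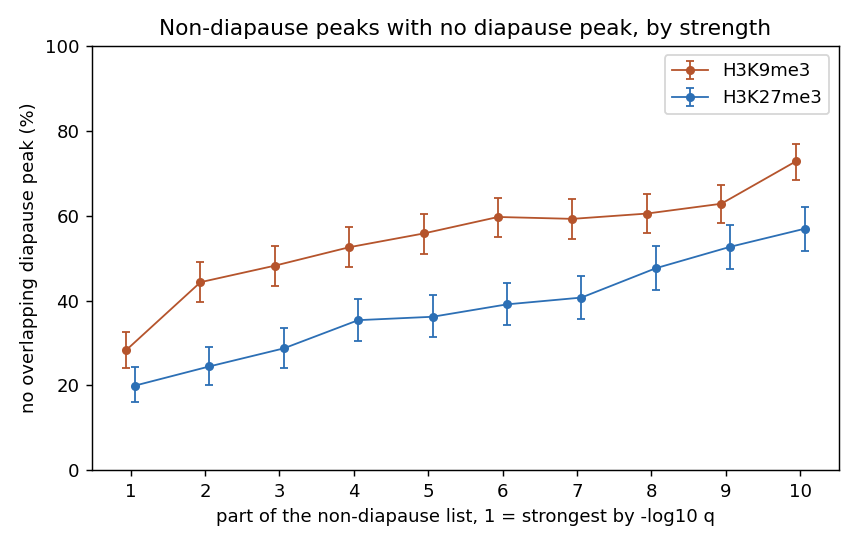
Share of non-diapause peaks with no overlapping diapause peak (vertical axis, %) in 10 parts of each non-diapause list, from the strongest to the weakest by −log10 q (horizontal axis), for H3K9me3 and H3K27me3, with exact 95% intervals as bars. The share runs from 28.3% to 72.8% for H3K9me3 and from 19.9% to 56.9% for H3K27me3.

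Pre-diapause lists took in most of the non-diapause places and added more. Of the non-diapause peaks 83.9% (82.8–85.0) for H3K9me3 and 90.3% (89.3–91.2) for H3K27me3 overlapped a pre-diapause peak. Among the strongest 10% of non-diapause peaks only 0.445% (0.0540–1.60) and 0.0% (up to 0.976) had none. In turn 51.5% (50.4–52.7) and 51.3% (50.1–52.5) of the pre-diapause peaks overlapped a non-diapause peak, which left 3503 and 3186 that did not. The strongest of these were weaker than the strongest peaks of their lists. For H3K9me3 they were NW_021131459.1 70–404, with a fold of 10.0, and NW_021133324.1 190737–191364, with 6.77. For H3K27me3 they were NW_021131459.1 82–399, with 9.64, and NW_021130331.1 266073–266510, with 8.37. Peaks called at non-diapause and not at pre-diapause numbered 721 and 364. The strongest of them, on NW_021134528.1 at 77–586 for H3K9me3 (fold 7.72) and at 136–586 for H3K27me3 (5.35), had peaks of both marks at diapause again. NW_021130959.1 had a non-diapause peak of H3K9me3 at 218761–219488 (5.63) and of H3K27me3 at 219145–219470 (4.91), and no peak at the other stages.

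In the lists as deposited, most diapause peaks met a pre-diapause peak, while most pre-diapause peaks, in lists far longer, met no diapause peak. Of the diapause peaks 75.6% (74.2–77.0) for H3K9me3 and 79.2% (77.9–80.5) for H3K27me3 overlapped a pre-diapause peak, and 36.3% (35.2–37.4) and 45.9% (44.7–47.1) of the pre-diapause peaks overlapped a diapause peak. A total of 4604 and 3536 pre-diapause peaks had no diapause peak. The strongest H3K9me3 ones lay at NW_021134144.1 486505–487597 (fold 17.8) and NW_021131933.1 124447–124996 (15.3). For H3K27me3 they lay at NW_021131933.1 124448–124995 (14.6) and NW_021131106.1 132054–133474 (14.1). Diapause peaks without a pre-diapause peak numbered 854 and 794. For H3K9me3 the strongest were NW_021134528.1 77–641 (7.78) and the peak on NW_021137676.1 (5.45), and for H3K27me3 the peak on NW_021133079.1 (5.96) and NW_021134528.1 158–550 (5.93).

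Lists of equal length changed the order of these shares. With the 3505 strongest peaks of each list, 66.7% (65.1–68.3) of pre-diapause H3K9me3 peaks overlapped a non-diapause peak. For diapause H3K9me3 peaks the share was 49.1% (47.4–50.8) against non-diapause and 50.4% (48.8–52.1) against pre-diapause. For H3K27me3 the shares were 68.5% (66.9–70.0), 61.4% (59.8–63.0) and 56.8% (55.1–58.5) in the same order. Of the pre-diapause peaks in these lists 49.6% (47.9–51.3) for H3K9me3 and 56.5% (54.9–58.2) for H3K27me3 overlapped a diapause peak, so the majority without a diapause peak was lost for H3K27me3 and within counting error of an even split for H3K9me3. By these shares, non-diapause and pre-diapause lists of equal length were nearer to each other than either was to diapause, for both marks. Equal length was not equal strength. The weakest peak kept had a −log10 q of 4.02, 6.64 and 2.05 for H3K9me3 in stage order, and 2.70, 6.42 and 2.70 for H3K27me3. Weak peaks met a partner less often between every pair of stages, so the weaker diapause H3K9me3 list could look farther for this alone.

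**Figure D2:**
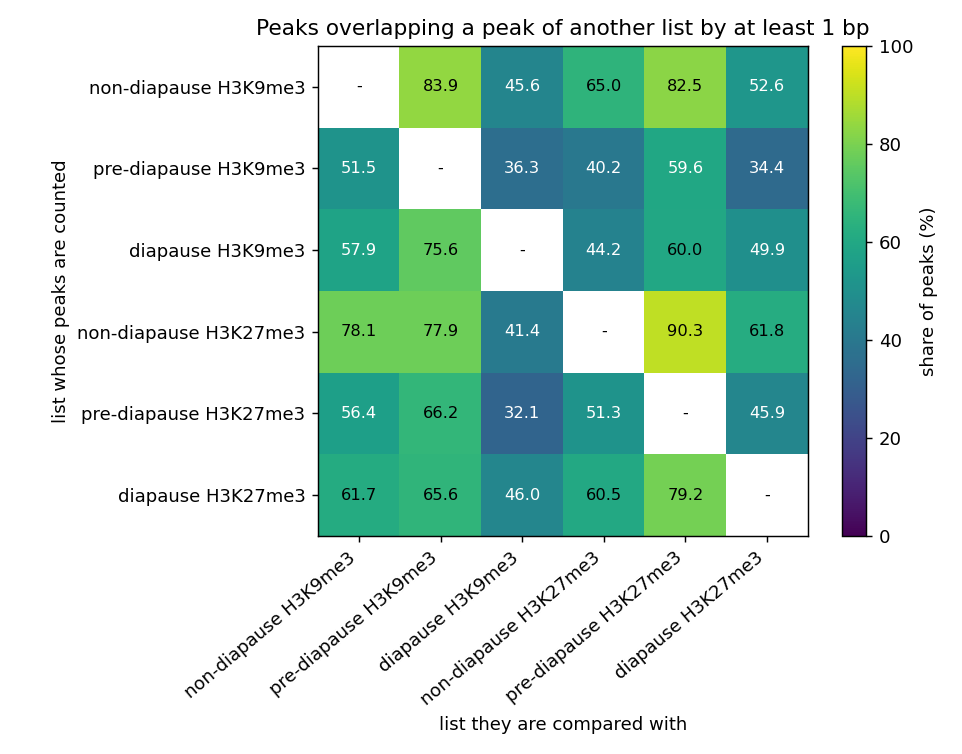
Share of the peaks of each list (vertical axis) that overlapped a peak of each other list (horizontal axis) by at least 1 bp, in percent by colour and number, for the 6 lists as deposited. The highest share is 90.3%, non-diapause H3K27me3 peaks in the pre-diapause list of that mark, and the lowest is 32.1%, pre-diapause H3K27me3 peaks in the diapause H3K9me3 list.

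Merged over the stages, the H3K9me3 lists made 8631 places and the H3K27me3 lists 7571. A peak was called at all 3 stages in 1873 H3K9me3 places, or 21.7% (20.8–22.6), and in 2207 H3K27me3 places, or 29.2% (28.1–30.2). The largest class was called at pre-diapause only, with 31.9% (30.9–32.9) and 31.6% (30.6–32.7) of the places. Places shared by non-diapause and diapause and missing at pre-diapause were the rarest, with 147 and 91. Ranked by the lowest fold over the stages, the strongest H3K9me3 peak at all 3 stages lay at NW_021131699.1 18940–20638. Its folds were 14.2, 13.2 and 14.9 in stage order. NW_021134443.1 97597–98229 followed with 12.5, 18.6 and 9.96, then NW_021136498.1 576–1850 with 11.4, 9.25 and 11.7. NW_021137592.1 43633–44204 had 14.6, 10.9 and 8.93, and NW_021137400.1 161046–161861 had 10.6, 11.6 and 7.79. By the same measure the strongest H3K27me3 place lay at the start of scaffold NW_021134836.1, at 1–881, with folds of 19.4, 32.4 and 24.8. H3K9me3 folds there were 28.6, 39.7 and 4.36, and the diapause H3K9me3 peak was still a strong call, with a −log10 q of 81.8. Next were NW_021137194.1 1095–1613 with 12.9, 9.75 and 10.9, NW_021131699.1 18989–20572 with 9.61, 9.78 and 14.5, NW_021134443.1 97606–98213 with 9.49, 11.8 and 10.96, and NW_021136407.1 76421–76963 with 9.13, 12.4 and 16.5. Diapause H3K9me3 folds at NW_021137194.1 and NW_021136407.1 were 2.30 and 3.01, with a −log10 q of 13.9 and 46.7. Folds of different lists are not on a shared scale, so these low folds do not show a loss of H3K9me3.

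Peaks of the 2 marks overlapped far more often than under random placement. The share overlapping was highest at non-diapause and lowest at diapause. Of the H3K27me3 peaks 78.1% (76.7–79.4) at non-diapause, 66.2% (65.0–67.4) at pre-diapause and 46.0% (44.4–47.6) at diapause overlapped an H3K9me3 peak of that stage. The shares of H3K9me3 peaks overlapping H3K27me3 peaks were 65.0% (63.5–66.4), 59.6% (58.5–60.8) and 49.9% (48.2–51.6). Random placement gave between 2.49% and 4.19% for these 6 shares. Set against it, they were 22.8, 15.8 and 18.4 times chance for H3K27me3 peaks and 23.0, 15.8 and 18.3 times for H3K9me3 peaks. By that measure pre-diapause, with the longest lists, was lowest. With the 3505 strongest peaks of each list the H3K27me3 shares were 23.6, 19.8 and 18.8 times chance in stage order. The H3K9me3 shares were then 24.0, 19.8 and 18.6 times chance. At equal length diapause was thus lowest, so the place of pre-diapause depended on list length. Of the 10959 places merged over all lists, 5181 (47.3%) had peaks of both marks at some stage, 3435 (31.3%) of H3K9me3 only and 2343 (21.4%) of H3K27me3 only. Peaks of both marks at all stages were found in 1206 places. Places of a single mark at all 3 stages were few, 141 for H3K9me3 and 221 for H3K27me3.

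Peaks that never met the other mark made up a minority of every list. H3K9me3 peaks that overlapped no H3K27me3 peak at any stage numbered 573 (12.8%) at non-diapause, 2689 (37.2%) at pre-diapause and 1192 (34.0%) at diapause. H3K27me3 peaks that overlapped no H3K9me3 peak numbered 578 (15.4%), 1720 (26.3%) and 970 (25.4%). Their median −log10 q was 3.83, 4.61 and 4.13 for H3K9me3 in stage order and 3.53, 4.29 and 3.44 for H3K27me3, below the 6.44, 6.49, 5.37, 6.42, 6.82 and 5.38 of the whole lists. Between these shortened lists, 14.5% of diapause H3K9me3 peaks and 28.5% of diapause H3K27me3 peaks overlapped a non-diapause peak. Shares between shorter lists are lower by construction, and set against random placement they were 18.9 times chance for H3K9me3, against 18.0 in the whole lists, and 13.6 times for H3K27me3, against 19.8.

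A stretch of scaffold NW_021135154.1, 0.9 Mb long at 1200001–2100000, held many H3K27me3 peaks and almost no H3K9me3 peaks. This block was picked for its windows dense in H3K27me3 peaks, so its excess of that mark follows in part from the choice. It makes up 0.240% of the spans and held 75 H3K27me3 peaks at non-diapause, 111 at pre-diapause and 114 at diapause, which is 1.99% (1.57–2.49), 1.70% (1.40–2.04) and 2.99% (2.47–3.58) of the lists. H3K9me3 peaks in it numbered 2, 1 and 2. H3K27me3 peaks covered 6.74, 10.99 and 10.5% of the block, with a median fold of 2.75, 2.77 and 2.86. Of the non-diapause peaks in the block 62.7% (50.7–73.6) overlapped a diapause peak and 68.0% (56.2–78.3) a pre-diapause peak, and of the diapause peaks 39.5% (30.4–49.1) overlapped a non-diapause peak and 52.6% (43.1–62.1) a pre-diapause peak. Of the pre-diapause peaks 42.3% (33.0–52.1) overlapped a non-diapause and 50.5% (40.8–60.1) a diapause peak. The peaks were weak ones: with −log10 q of at least 3 the block held 40, 71 and 67, and among the 3505 strongest peaks of each list 50, 4 and 85.

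**Figure D3:**
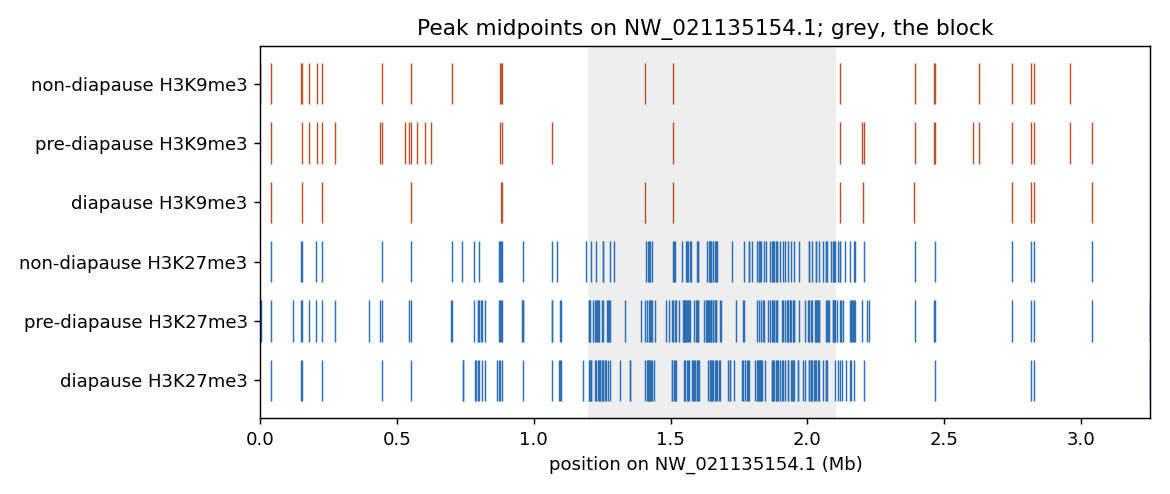
Midpoints of the peaks of the 6 lists along scaffold NW_021135154.1 (horizontal axis, Mb), with 1 line per peak and the block from 1200001 to 2100000 in grey. The grey stretch holds 75, 111 and 114 H3K27me3 peaks at non-diapause, pre-diapause and diapause, and 2, 1 and 2 H3K9me3 peaks.

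The sequence taken here, from its RefSeq name and its length, as the mitochondrial genome had peaks in all 6 lists. Mitochondrial DNA is known not to be packaged on histones. They covered 89.7, 99.8 and 99.8% of the 14536 bp span in the H3K9me3 lists in stage order, and 65.4, 99.9 and 99.99% in the H3K27me3 lists. The fold was 10.5 and 11.4 in the diapause lists of H3K9me3 and H3K27me3, 5.62 and 4.97 in the pre-diapause lists, and at most 6.26 and 4.46 in the non-diapause lists.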

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

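The tests of explanations in this part were chosen after the pattern they bear on had been seen, while the stricter −log10 q and the lists of equal length were set before the data were examined. The count of H3K9me3 peaks differed by -981 between diapause and non-diapause, 3505 against 4486, while that of H3K27me3 differed by 53, 3813 against 3760, so the list lengths differed in opposite directions. This difference between the marks was not tested, since each count comes from 1 list. With −log10 q of at least 3 the differences were -1083 and -75, and the direction no longer differed.

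Between 46.0 and 78.1% of the H3K27me3 peaks of a stage overlapped an H3K9me3 peak of that stage. A chromatin preparation or input shared within a stage would raise the share with same-stage H3K9me3 peaks above that with other stages. In lists of equal length the same stage less the best other was -9.19 percentage points at diapause (48.9 against 58.1%). As deposited the same stage was also lower, 46.0% against 61.7% with non-diapause and 65.6% with pre-diapause peaks, but those H3K9me3 lists were longer. At equal length the diapause share with pre-diapause peaks was 47.9% (46.2–49.6), within counting error of the same stage. At pre-diapause the same stage less the best other was -5.71 points (64.8 against 70.5%), but as deposited the same stage was higher, 66.2 against 56.4%. Equal length cut the pre-diapause H3K9me3 list at −log10 q of 6.64 and the non-diapause list at 4.02, so pre-diapause decides nothing. The diapause list was uncut and reached 2.05, which limits the argument there. At non-diapause it was 14.3 points (73.4 against 59.1%), and 78.1 against 77.9% as deposited. A shared preparation thus stays open at pre-diapause and non-diapause. Sites enriched whatever the antibody, such as repeats collapsed in the assembly, stay open and would put the strongest peaks at shared places most often. Among the strongest 10% of H3K27me3 peaks 99.5, 99.7 and 81.7% overlapped an H3K9me3 peak of that stage in stage order, above the 78.1, 66.2 and 46.0% of the whole lists, and the sequence taken as the mitochondrial genome also had peaks of both marks. Both marks on the same stretches of chromatin, or on the same stretches in different cells of the head, could give this too and were not tested.

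The block on NW_021135154.1 was rich in H3K27me3 peaks at every stage, which follows in part from how it was picked. Sites enriched whatever the antibody are argued against, since at most 0.0571% of an H3K9me3 list lay in it, with upper bounds of 0.161, 0.0771 and 0.206% in stage order, all below its 0.240% of the spans. A broad Polycomb domain is a hypothesis that was not tested. The genes of the block were not analysed here, and whether the block changes with stage stays open, since its peaks were weak and only 4 of them were among the 3505 strongest pre-diapause peaks.

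Some strong non-diapause peaks lacked a diapause peak. Signal nearer the threshold at diapause, from lower depth or enrichment, stays open. The share missing was higher by 44.5 percentage points for H3K9me3 and 37.0 for H3K27me3 in the weakest 10% than in the strongest 10%. Weak peaks lacked a partner more often between every pair of stages, so this decides nothing. Against the longer pre-diapause lists the share missing rose from 0.445 to 39.5% for H3K9me3 and from 0.0 to 33.0% for H3K27me3. How many of the strongest peaks a signal nearer the threshold could remove was not tested, since depth is unknown. Of the strongest 10%, 28.3% (24.2–32.7) for H3K9me3 and 19.9% (16.0–24.3) for H3K27me3 were missing at diapause. Sites enriched whatever the antibody, or differing in copy number, cannot be told apart from a change in the marks. Of 127 strong H3K9me3 peaks missing at diapause, 48.8% (39.9–57.8) lacked a diapause H3K27me3 peak as well. In the whole non-diapause H3K9me3 list 2127 of 4486 peaks lacked one. Of 75 strong H3K27me3 peaks missing at diapause 77.3% (66.2–86.2) lacked a diapause H3K9me3 peak, beside 2204 of 3760 in the whole list. The whole lists take in weak peaks, which lacked a partner more often, so they are no baseline of like strength. Whether strong peaks lost both marks together more often than expected thus stays open. The diapause state itself stays open as well, untested without replicates.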

How the results depend on the processing

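The alternatives that kept only peaks of 1 mark or left out the mitochondrial sequence, and the counts in the block, were chosen after the data were seen; the others were fixed beforehand. The 6 list lengths stayed within 1.5 times of the deposited ones at −log10 q of at least 3. Below, stage shares are in the order diapause in non-diapause, non-diapause in diapause, pre-diapause in non-diapause, non-diapause in pre-diapause, diapause in pre-diapause and pre-diapause in diapause. With −log10 q of at least 3, 7 of 18 shares stayed within their interval and none moved by more than 3.34 points. Those that moved were for H3K9me3 non-diapause in diapause (43.8%), diapause in pre-diapause (77.2%) and pre-diapause in diapause (34.9%), and for H3K27me3 non-diapause in pre-diapause (91.4%), diapause in pre-diapause (82.0%) and pre-diapause in diapause (44.7%). The share of H3K27me3 peaks on H3K9me3 peaks moved to 81.4, 67.5 and 47.9% in stage order, and the reverse share to 61.0% at pre-diapause and 51.9% at diapause. An overlap of at least 50% of the peak lowered all 18 shares by up to 5.72 points, as a narrower rule must. The stage shares became 53.0, 41.4, 46.6, 81.5, 72.4 and 31.3% for H3K9me3 and 54.8, 57.0, 45.6, 88.1, 74.9 and 40.6% for H3K27me3. H3K27me3 peaks on H3K9me3 peaks became 76.7, 63.7 and 43.4%, and the reverse 60.5, 55.6 and 45.5%. With 3505 peaks in every list, 15 shares moved, by up to 25.2 points; by construction this shortened the pre-diapause lists most. H3K9me3 stage shares became 49.1, 49.2, 66.7, 67.4, 50.4 and 49.6%. For H3K27me3 the pairs with pre-diapause became 68.5, 69.1, 56.8 and 56.5%, and the other 2 kept within their interval. H3K27me3 peaks on H3K9me3 peaks became 73.4, 64.8 and 48.9%, and the reverse 72.8% at non-diapause and 64.6% at pre-diapause. Keeping only peaks of 1 mark lowered all 12 stage shares, to 14.5, 30.4, 11.5, 54.5, 53.4 and 23.4% for H3K9me3 and 28.5, 49.8, 20.8, 64.0, 48.4 and 27.0% for H3K27me3. Lists so shortened overlap less by construction, and these shares were 11.5 to 21.1 times the mean of random placements. Leaving out the mitochondrial sequence moved no share by more than 0.0508 points. It held at most 5 peaks of a list, so shares could hardly move, and sites enriched whatever the antibody elsewhere were not tested by this. The alternatives set for genes near peaks were not run, because genes could not be placed. No paired analysis was possible because there was 1 list for each mark and stage and no test. Depth is unknown, so the number of peaks a deeper library would give is open.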

Other observations

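The hypothesis in the last paragraph and its test over the whole list by strength were written before the result was seen, while its repeats and the other places and windows given here were chosen after the data were seen. Of the 10959 places merged over all lists, 611 or 5.58% (5.15–6.02) had peaks of both marks at non-diapause and pre-diapause and of neither mark at diapause. A further 543 had both marks at pre-diapause and no other peak. Places with both marks at diapause and no other peak numbered 68, and those with both marks at non-diapause alone 36. The peak on NW_021134144.1 at 486505–487597 was the strongest of the pre-diapause H3K9me3 peaks without a diapause peak, with H3K9me3 folds of 5.60 at non-diapause and 17.8 at pre-diapause and no diapause peak, and H3K27me3 folds of 4.34 and 11.1 and no diapause peak.

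Other stretches of 100 kb were dense in H3K27me3 peaks at all stages. NW_021131364.1 at 1–100000 held 11, 23 and 18 H3K27me3 peaks in stage order, beside 2, 2 and 4 of H3K9me3. NW_021131485.1 at 500001–600000 held 13, 14 and 16, which covered 16.7, 37.1 and 31.7% of it, beside 0, 1 and 0 of H3K9me3. A window of the opposite kind, NW_021133039.1 at 600001–700000, held 1 H3K9me3 peak at non-diapause and 12 at both pre-diapause and diapause, beside 0, 1 and 0 of H3K27me3. This window was dense by the rule at diapause only, since random placements reached 9 there and 13 at pre-diapause. Its high diapause count follows in part from that choice. The median fold of its H3K9me3 peaks was 2.06 at pre-diapause and 1.84 at diapause. NW_021135248.1 at 1–100000 held 4, 15 and 3 H3K9me3 peaks and was dense by the rule at pre-diapause only.

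If H3K27me3 peaks away from H3K9me3 peaks were the more lasting ones, more of them would be found again at diapause than of peaks of like strength shared with H3K9me3. The prediction was made within 3 equal parts of the non-diapause list by −log10 q, and no part showed the predicted excess. From the strongest part to the weakest, the shares overlapping a diapause H3K27me3 peak were 67.9% without H3K9me3 at any stage against 75.1% of the others, 52.3 against 63.4%, and 48.1 against 48.4%. The lowest difference was -11.2 percentage points, and the intervals overlapped in each part. With the block on NW_021135154.1 left out, the shares were 65.4 against 75.1%, 48.3% (39.1–57.6) against 63.4% (60.5–66.3), and 46.9 against 48.4%. The intervals were then apart in the middle part, against the hypothesis. That split takes in H3K9me3 peaks at diapause, the stage of the outcome, which works against the hypothesis. It therefore decides nothing, with the block or without it. Split by H3K9me3 at non-diapause alone, the shares were 54.3% (39.0–69.1) without against 75.7% (73.2–78.1) with it, 48.3% (41.4–55.3) against 65.1% (62.1–68.0), and 46.0% (41.9–50.2) against 50.1% (46.3–54.0). The lowest difference was -21.4 points, and the intervals were apart in the stronger 2 of the 3 parts. That goes against the hypothesis for peaks as called. Sites enriched whatever the antibody, left open above, would have both marks and recur, so it does not settle how lasting the mark is. Parts of a list match strength only roughly, and each list stands for 1 sample.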
